A study of Mus musculus with 3 samples.

How the data were processed

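RNA from cultured mouse dermal fibroblasts of 3 genotypes was measured on Affymetrix expression arrays. The series holds 3 samples, 1 per genotype. In FGFR3Act the receptor Fgfr3 carries the G374R change and signals without ligand. FGFR3KO cells carry the same allele with the neo cassette retained and, per the labels, make no functional receptor. FGFR3WT cells came from wild-type Bl6 mice. Biotin-labelled cRNA was prepared from 15 μg of total RNA, per the labels' protocols.

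The deposited table gives 1 intensity per probe set and sample. Per the submitters' processing notes these values were made with MAS5, Affymetrix's algorithm that summarises the probe pairs of a probe set into 1 signal and scales each array by 1 factor. The version, the scaling target and the detection calls are not given in the sources used here. The deposited intensities are linear and positive. Their means after trimming 2% at each end were 613 for FGFR3Act, 606 for FGFR3KO and 614 for FGFR3WT, which lie close together. The series states n = 3 for each group, while the table has 1 column per group. Whether a column is 1 culture, a pool or a mean of 3 is not given, so no error between replicates could be computed. No p-value, SD or standard error is attached to a difference between genotypes for that reason. The number of arrays limits the precision of each value.

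The table has 9889 probe sets, of which 18 are control probe sets. GEO's platform annotation lists 9376 of them, 9053 with 1 gene symbol and 323 with several. Symbols were updated through their gene identifiers with the RefSeq table of assembly GRCm38.p6, in which 9041 of the 9053 were matched. No probe set with several symbols or none was named. This left 7842 genes, 1001 of them with more than 1 probe set. Each gene was represented by its probe set with the highest mean log2 signal over the 3 arrays.

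Low MAS5 signals are noisy. Without detection calls, a floor was set at the 40th percentile of the non-control probe sets of each array. It lay at 123 for FGFR3Act, 122 for FGFR3KO and 121 for FGFR3WT. Signals under the floor were raised to it before log2 was taken, no further scaling was applied, and a gene entered a pair of arrays if it was above the floor on at least one of them. A fold against an array at the floor is given as "at least". All differences are on the log2 signal scale, and raising signals to the floor makes differences of dim probe sets smaller.

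The 3 possible pairs of arrays were compared: FGFR3Act with FGFR3WT, FGFR3KO with FGFR3WT, and FGFR3Act with FGFR3KO. Genes at least 2-fold apart were counted, as a description of size and not a test. A set of 40 gene lists was fixed before the data were examined. For each list with at least 3 members in a pair, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from genes of similar mean signal in 20 bins. A list is said to stand apart where it lies below percentile 2.5 or above 97.5. Chance places 5% of lists of separately drawn genes there. Genes of a real list can vary together between cultures, so such lists may stand apart more often without an effect of genotype. Such a percentile describes these arrays and is not a p-value for the genotype.

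The rule for named genes was also fixed before the data were examined. It takes Fgfr3 first. For each mutant against FGFR3WT it then takes the 10 genes furthest apart in each direction, and for FGFR3Act against FGFR3KO the 5. These had to be at least 2-fold apart and above the floor on both arrays, with their other measured probe sets in the same direction, and clone names were left out. It also takes up to 10 genes in each direction that are at least 2-fold from FGFR3WT in opposite directions in the 2 mutants, and the 2 to 4 members furthest apart in each list described. Genes named beyond this rule, to complete a count of 5 or fewer or because a comparison is commonly read from them (Col1a1, Col1a2, Acta2, Ccn2, Ccn1, Edn1, Il4ra, Tpsb2, Cma1), were chosen after their values were seen.

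Alternatives fixed beforehand were quantile normalisation, cyclic loess and median centring, floors at the 20th and 60th percentiles, log2 of signal plus an offset of 12.0 with no floor, a filter for both arrays above the floor, no filter, the mean over a gene's probe sets, and leaving out probe sets of the _s_ and _x_ kinds. An alternative without macrophage genes was added after the data were seen. It left out the macrophage and leukocyte marker list, C1qa, C1qb and C1qc and a second macrophage list described below. Other genes, such as the macrophage elastase Mmp12, stayed in. The arithmetic was tested on simulated arrays with a noise SD of 0.35 per array in log2, a level chosen for the simulation. In 4947 simulated genes, as many as were above the floor on FGFR3WT, the 2-fold threshold recovered 49.5% of 200 genes changed 2-fold, 98.5% changed 4-fold and 100% changed 8-fold, and took in 4.51% of the unchanged genes in the 2-fold simulation. Of 200 simulated lists of 15 unchanged genes, 4% stood apart, and 90% of 50 lists shifted by 0.5 did. These rates check the arithmetic and are not error rates for real lists, whose genes can vary together. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1 for normalisation, and matplotlib 3.10.9.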

Results

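Gene expression was measured in cultured dermal fibroblasts with a constitutively active Fgfr3 (FGFR3Act), without a functional Fgfr3 (FGFR3KO) or with the wild-type gene (FGFR3WT). Fgfr3 is a receptor tyrosine kinase for fibroblast growth factors, and the study asked how its signalling bears on the profibrotic program of fibroblasts. Each genotype had 1 array column. Of 7842 named genes, 4932 were above the floor on FGFR3Act, 4967 on FGFR3KO and 4947 on FGFR3WT, and 4503 on all 3. Over the 4947 named probe sets above the floor on every array, log2 signals correlated across probe sets, which are not independent replicates, at r = 0.939 between FGFR3KO and FGFR3WT, 0.922 between FGFR3Act and FGFR3WT, and 0.877 between FGFR3Act and FGFR3KO. There were no replicate arrays, so every difference below is one between arrays, with no check against the spread between cultures.

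The targeted gene could not check the genotypes. Fgfr3 was represented by 1 probe set, with signals of 2.42 on FGFR3Act, 3.76 on FGFR3KO and 1.06 on FGFR3WT, far below the floor on each array. Of the 13 FGF receptors, co-receptors and ligands on the array, 4 could be compared in each pair, and their median lay within the range of random lists in all 3 pairs. Fgf7, a growth factor that fibroblasts secrete for epithelium, was 3.85-fold higher on FGFR3Act than on FGFR3WT. Fgfr2 was 1.89-fold higher on FGFR3KO than on FGFR3WT.

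The first comparison asked what accompanied constitutive Fgfr3 activity. Macrophage transcripts, chemokines, CREB targets and the list of FGF-ERK feedback and immediate targets were higher on FGFR3Act than on FGFR3WT. Mitotic, cholesterol synthesis, collagen, matrix glycoprotein and contractile genes were lower. Elastin (Eln) had a signal of 556 on FGFR3Act against 6604 on FGFR3WT, and the lipid carrier Apoe 14585 against 245. Because the array also held macrophage transcripts, whether macrophages or fibroblasts made Apoe and the other higher transcripts cannot be told apart. Of 5244 genes, 217 were at least 2-fold higher on FGFR3Act and 251 at least 2-fold lower. Which side had more genes depended on the scaling, with 231 higher and 212 lower after quantile normalisation, 248 and 194 after median centring and 246 and 195 after cyclic loess. The 10 genes furthest above wild type were Apoe (59.6-fold), the chitinase-like Chil1 (15.0-fold), the regulator of G-protein signalling Rgs16 (9.20-fold), the chemokine Ccl9 (9.10-fold), the myeloid receptor Cd300c2 (8.67-fold), the peptide hormone gene Cck (8.51-fold), the chromatin protein Hmga2 (8.45-fold), the Kit ligand Kitl (8.11-fold), the retinaldehyde dehydrogenase Aldh1a1 (6.96-fold) and the oxysterol-producing Ch25h (6.23-fold). The 10 furthest below were Eln (11.9-fold lower), Mest (9.09-fold), the collagen-binding fibromodulin Fmod (7.91-fold), the glucocorticoid-activating enzyme Hsd11b1 (7.44-fold), Nrep (7.37-fold), Fndc1 (6.60-fold), the microfibril protein Mfap2 (6.31-fold), the homeobox gene Meox2 (5.89-fold), the cytokinesis kinesin Kif23 (5.53-fold) and the secreted peroxidase Gpx3 (5.02-fold). Of these, Hsd11b1, Nrep and Meox2 were also at least 2-fold lower on FGFR3KO than on FGFR3WT.

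**Figure D1:**
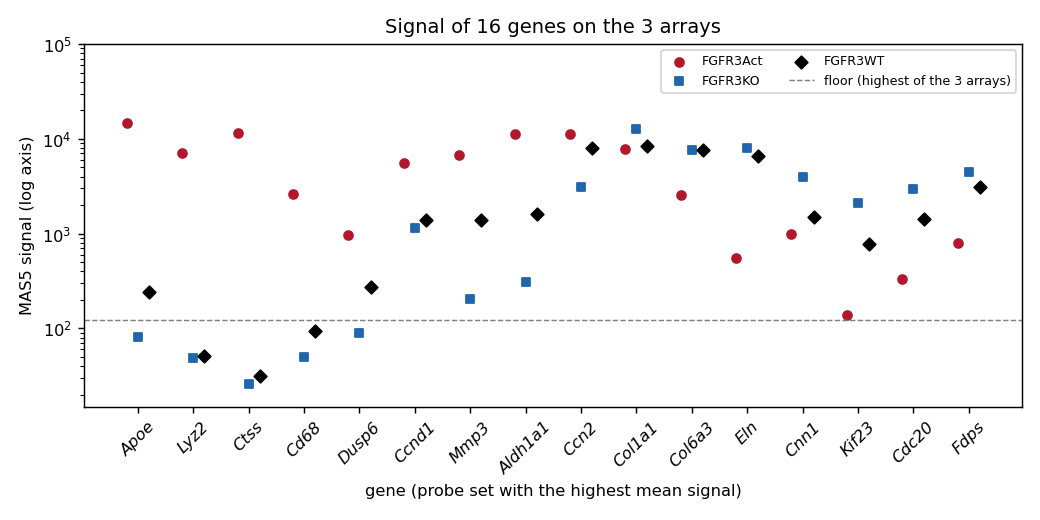
MAS5 signal on a log axis of 16 genes on the FGFR3Act, FGFR3KO and FGFR3WT arrays, 1 point per array, with the highest of the 3 floors as a dashed line. Lyz2, Ctss and Cd68 are above the floor on FGFR3Act alone, Dusp6, Mmp3 and Aldh1a1 are highest on FGFR3Act and lowest on FGFR3KO, and Cnn1, Kif23, Cdc20 and Fdps run the other way.

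Markers of macrophages set the FGFR3Act array apart from the other 2 arrays. Of 22 macrophage and leukocyte markers on the array, 13 could be compared with FGFR3WT. Of these 11 were at least 2-fold higher on FGFR3Act and 0 at least 2-fold lower, with a median log2 difference of 2.87 (percentile 100 among matched random lists). Lysozyme (Lyz2) had a signal of 7037 on FGFR3Act, at least 58.3-fold above FGFR3WT, and was below the floor on FGFR3WT and FGFR3KO. The lysosomal protein gene Cd68 was at least 21.6-fold higher, the leukocyte membrane protein gene Cd53 at least 15.0-fold and Csf1r, the receptor for macrophage colony-stimulating factor, at least 12.0-fold. Of the mast cell protease genes, Cma1 was at least 1.83-fold higher and Tpsb2 1.09-fold lower. With genes below the floor on both arrays included, the median over all 22 was 0.98, still at percentile 100. General fibroblast markers did not stand apart, with a median of -0.11 over 13 members (percentile 22.8).

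Feedback and immediate targets of FGF-ERK signalling were higher on FGFR3Act as a group, on the array that also held the macrophage markers (median 2.87). Of 16 members, 5 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.42 (percentile 99.9). The EGF receptor ligand Ereg was at least 4.38-fold higher, cyclin D1 (Ccnd1) 3.94-fold, the ERK phosphatase Dusp6 3.51-fold, the AP-1 subunit Fosl1 3.32-fold and the ligand gene Hbegf 2.02-fold. Among 12 CREB targets, 3 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.64 (percentile 100). The prostaglandin synthase Ptgs2 was 3.32-fold higher, the transcription factor Atf3 3.08-fold and Crem 2.33-fold, and Nfil3 was at least 2.53-fold lower.

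Inflammatory, protease and complement genes were higher on the same FGFR3Act array that held the macrophage markers (median 2.87). Of 20 cytokine and chemokine genes, 10 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.94 (percentile 100). Lipocalin 2 (Lcn2) was at least 10.3-fold higher, Ccl9 9.10-fold, the neutrophil chemokine Cxcl1 5.22-fold and the acute-phase gene Saa3 3.76-fold. Of 18 matrix proteases and inhibitors, 4 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.56 (percentile 100). Cathepsin S (Ctss) was at least 94.6-fold higher, the macrophage elastase Mmp12 at least 41.7-fold, stromelysin (Mmp3) 4.79-fold and the urokinase receptor gene Plaur 2.56-fold, and Mmp11 was 2.39-fold lower. The complement list had a median of 0.63 (percentile 99.9), and the 3 of its 8 members at least 2-fold higher were C1qa (at least 15.6-fold), C1qb (at least 11.1-fold) and C1qc (at least 18.2-fold), all made by macrophages. A setting chosen after the data were seen left out the marker list, C1qa, C1qb and C1qc and a second macrophage list described below. It left 182 genes at least 2-fold higher, with Ctss, Mmp12 and Ccl9 still among them, so that count is not free of macrophage transcripts. The complement median was then -0.0619, as the 3 members that had raised it were among the genes removed.

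Matrix genes were lower on FGFR3Act, again on the array that held the macrophage markers (median 2.87). Among 11 collagens of the fibrous matrix, 3 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.69 (percentile 0.01). These were Col6a2 (3.85-fold), Col6a3 (3.00-fold) and Col8a1 (2.14-fold). The genes of the main fibrillar collagen were close to wild type, with log2 differences of -0.11 for Col1a1 and -0.15 for Col1a2. Of 17 matrix glycoproteins, proteoglycans and elastic fibre genes, 5 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.42 (percentile 0.17). The 5 were Eln, Fmod, Mfap2, the fibrillin gene Fbn2 (at least 4.02-fold) and the proteoglycan gene Vcan (2.88-fold), and the 1 was tenascin C (Tnc, 2.03-fold). Basement membrane genes had a median of -0.47 (percentile 0.32), with nidogen Nid2 2.29-fold lower. Collagen processing genes had a median of -0.44 (percentile 1.44), with the procollagen proteinase Bmp1 3.18-fold and its enhancer Pcolce 2.21-fold lower. With the floor at the 20th percentile the last 2 lists lay inside the random range, with medians of -0.35 and -0.34.

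Contractile genes had a median of -0.54 (percentile 0) on FGFR3Act, where the macrophage markers were higher (median 2.87), with 3 of 16 at least 2-fold lower and 0 at least 2-fold higher. The 3 were the actin genes Acta1 (3.80-fold) and Actg2 (2.57-fold) and Pdlim7 (2.02-fold). The myofibroblast marker Acta2 was 1.21-fold higher. TGF-beta targets and pathway genes had a median of 0.23 (percentile 98.6), with Id2 6.19-fold and the activin subunit gene Inhba 2.55-fold higher and Tgfb2 2.13-fold lower among 20 members. The median of TGF-beta targets and pathway, FGFR3Act against FGFR3WT, did not stand apart with no filter (0.0472) or with an offset in place of the floor (0.13). Connective tissue growth factor (Ccn2) was 1.38-fold higher. Endothelin 1 (Edn1) was 1.39-fold higher and the interleukin-4 receptor gene Il4ra 1.84-fold lower. Il4ra was also lower on FGFR3KO than on FGFR3WT, by 2.49-fold. The 7 members of the interleukin-4 and interleukin-13 pathway did not stand apart (median -0.55, percentile 2.75), nor did the list on FGFR3KO (median -0.33, percentile 5.33).

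Mitotic and cholesterol synthesis genes were lower on FGFR3Act, the array with the higher macrophage markers (median 2.87). Mitotic genes were lower in 22 of 22 members, 14 of them at least 2-fold, with a median of -1.08 (percentile 0). Kif23 was 5.53-fold lower, cyclin B2 (Ccnb2) 4.48-fold, the anaphase activator Cdc20 4.27-fold and the spindle protein Prc1 3.10-fold. For 10 of the 22 the FGFR3Act signal was below the floor, so these differences are bounds. Replication genes did not stand apart (median -0.21, percentile 21.2), with Uhrf1 at least 2.19-fold and Rrm1 2.13-fold lower. Cholesterol synthesis genes were lower in 16 of 16 members, 8 of them at least 2-fold, with a median of -1.02 (percentile 0). Farnesyl diphosphate synthase (Fdps) was 3.93-fold lower, Nsdhl 2.55-fold and lanosterol synthase (Lss) 2.39-fold. Of 13 ribosomal protein genes, 3 were at least 2-fold lower, Rpl10a (3.10-fold), Rps10 (2.71-fold) and Rpsa (2.29-fold), and the median was -0.24 (percentile 1.54).

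The second comparison asked what accompanied the loss of Fgfr3 function. Mitotic, replication and contractile genes were higher on FGFR3KO than on FGFR3WT. By their medians, the list of FGF-ERK feedback and immediate targets and, slightly, the glycolysis and hypoxia list were lower. The stromelysin gene Mmp3 had a signal of 205 on FGFR3KO against 1405 on FGFR3WT, and the cyclin-dependent kinase inhibitor Cdkn1c 2315 against 479. Of 5184 genes, 100 were at least 2-fold higher on FGFR3KO and 187 at least 2-fold lower. Together they were 5.54% of the genes, against 8.92% in FGFR3Act against FGFR3WT. The simulation took in 4.51% of unchanged genes at a noise SD of 0.35. That level was chosen and not measured on these arrays, so how many of these genes reflect noise is not known. The 10 furthest above wild type were Cdkn1c (4.83-fold), Plac8 (4.70-fold), the alcohol dehydrogenase Adh1 (3.94-fold), Clca3a1 (3.72-fold), the mitotic kinesin Kifc1 (3.17-fold), H2-M10.1 (3.13-fold), Slc9a3r1 (3.10-fold), the mitochondrial import pore gene Tomm40 (3.06-fold), the replication-associated Pclaf (3.04-fold) and the mitotic kinase Ttk (2.87-fold). The 10 furthest below were Nrep (7.46-fold lower), Mmp3 (6.85-fold), Aldh1a1 (5.30-fold), the collagenase Mmp13 (4.91-fold), the chemokine receptor Ackr3 (4.62-fold), the thyroid hormone deiodinase Dio2 (4.53-fold), Fancc (4.34-fold), Bpgm (4.13-fold), the protein kinase A inhibitor Pkia (4.13-fold) and Yipf4 (3.96-fold). Of these, Nrep, Dio2 and Fancc were also at least 2-fold lower on FGFR3Act than on FGFR3WT.

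Mitotic genes were higher on FGFR3KO in 23 of 23 members, 9 of them at least 2-fold, with a median of 0.86 (percentile 100). Ttk was 2.87-fold higher, Kif23 2.76-fold, the spindle motor Kif11 2.55-fold and Tacc3 at least 2.23-fold. Replication genes had a median of 0.48 (percentile 99.99), were higher in 15 of 19 members, and held 1 gene at least 2-fold higher, cyclin E1 (Ccne1, 2.07-fold). Contractile genes were higher in 16 of 17 members, 2 of them at least 2-fold, with a median of 0.67 (percentile 100). Smooth muscle myosin (Myh11) was at least 3.06-fold and calponin (Cnn1) 2.61-fold higher, and Acta2 was 1.71-fold higher. On FGFR3KO the beta-actin control probe sets also stood above FGFR3WT, at 1.65, 1.62 and 1.48 times from the 3' to the 5' end, near the 1.59-fold median of the list, and those for 18S ribosomal RNA at 2.43, 1.65 and 2.44 times. On FGFR3Act, where the contractile median was lower, the beta-actin controls stood at 1.36, 1.42 and 1.55 times FGFR3WT. None of the 13 collagens of the fibrous matrix was 2-fold apart, and their median of 0.31 lay inside the random range (percentile 82.4).

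Of 15 FGF-ERK feedback and immediate targets, 0 were at least 2-fold higher on FGFR3KO and 4 at least 2-fold lower. Their median was -0.46 (percentile 0.605). Dusp6 was at least 2.26-fold lower, Bhlhe40 2.24-fold, Ier3 2.14-fold and Fos 2.04-fold. With the floor at the 60th percentile, which left 8 members, the list lay inside the random range (median -0.23, percentile 5.59). Glycolysis and hypoxia genes had a median of -0.20 (percentile 1.15), with adrenomedullin (Adm) 3.53-fold, the oxygen sensor gene Egln1 2.11-fold and Bnip3 2.08-fold lower among 22 members. Their median on FGFR3Act against the same FGFR3WT array was similar, at -0.18 (percentile 7.81), so this small shift was not particular to FGFR3KO. The TGF-beta list did not stand apart (median -0.04, percentile 50.1), and its 2 members at least 2-fold apart were Ccn2 (2.62-fold lower) and Ccn1 (2.51-fold lower). Matrix proteases and inhibitors did not stand apart either (median -0.18, percentile 5.35), with Mmp3, Mmp13 and the inhibitor gene Timp2 (2.42-fold) lower. Of the macrophage and leukocyte markers, 3 could be compared and 0 were 2-fold apart.

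**Figure D2:**
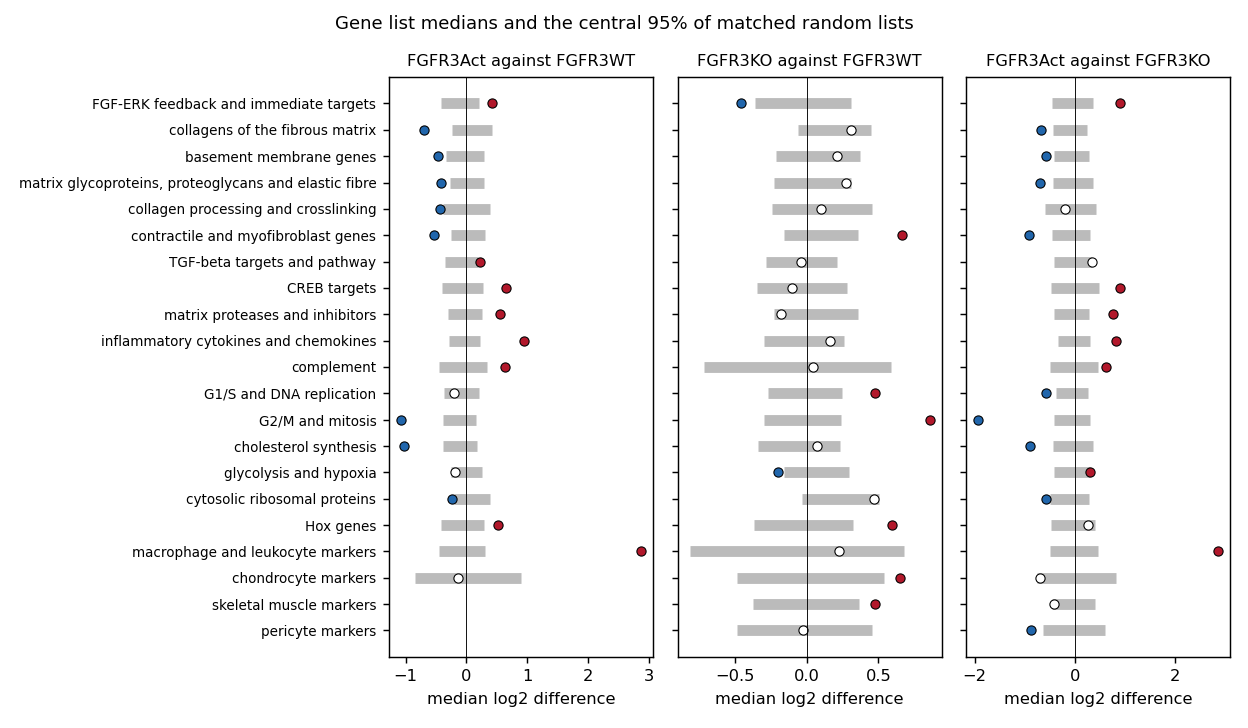
Median log2 difference of each list that stood apart in at least 1 pair of arrays (points, red above the random range, blue below it and white inside it), with the central 95% of 10000 matched random lists as grey bars; horizontal axes differ between panels, and a list with fewer than 3 members in a pair has no point there. Mitotic and contractile genes lie below the range for FGFR3Act and above it for FGFR3KO, and FGF-ERK feedback and immediate targets lie the other way.

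The third comparison set the active receptor against its loss and did not use the wild-type array. Aldh1a1, Mmp3 and the list of FGF-ERK feedback and immediate targets were higher on FGFR3Act than on FGFR3KO. Mitotic, contractile, collagen, matrix glycoprotein and cholesterol synthesis genes were lower. Of 5297 genes, 441 were at least 2-fold higher on FGFR3Act and 397 at least 2-fold lower. The 5 furthest above were Aldh1a1 (36.9-fold), Mmp3 (32.8-fold), Chil1 (15.0-fold), Ch25h (8.95-fold) and Hmga2 (8.07-fold). The 5 furthest below were Kif23 (15.3-fold lower), Eln (14.2-fold), Cdc20 (8.98-fold), Cdkn1c (8.46-fold) and Fmod (8.36-fold). Mitotic genes were lower in 23 of 23 members, 22 of them at least 2-fold, with a median of -1.93 (percentile 0). Of 19 replication genes 5 were at least 2-fold lower (median -0.57, percentile 0.14), led by Rrm1 (3.06-fold) and Uhrf1 (at least 3.05-fold).

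FGF-ERK feedback and immediate targets were at least 2-fold higher on FGFR3Act than on FGFR3KO in 8 of 16 members and at least 2-fold lower in 0. Their median was 0.90 (percentile 100). The feedback regulators Spry4 and Spred2 and the target Etv4 were slightly lower, with log2 differences of -0.02, -0.19 and -0.22. Dusp6 was at least 7.93-fold, Ccnd1 4.74-fold, Ereg at least 4.34-fold and Ier3 2.92-fold higher. The macrophage markers were higher on FGFR3Act in this pair too (median 2.86, percentile 100), as were inflammatory genes (9 of 20 at least 2-fold, median 0.82) and matrix proteases and inhibitors (7 of 18, median 0.76). The complement median of 0.61 rested on C1qa, C1qb and C1qc, the 3 of its 8 members at least 2-fold higher, and turned to -0.47 with both arrays above the floor and to -0.0794 without the macrophage genes. Ccl9 was at least 20.6-fold higher. The 12 CREB targets, with Ptgs2 4.27-fold higher, had a median of 0.91 (percentile 99.96), but lay inside the random range with the floor at the 20th percentile (median 0.33, percentile 93.6). The TGF-beta list did not stand apart (median 0.33, percentile 97.4), although Ccn2 was 3.60-fold and Ccn1 3.04-fold higher.

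Matrix and contractile genes were lower on FGFR3Act than on FGFR3KO, in the pair in which the macrophage markers were higher on FGFR3Act (median 2.86). Of 17 contractile genes, 7 were at least 2-fold lower (median -0.92, percentile 0), with Acta1 5.69-fold and Cnn1 3.93-fold lower. Of 13 collagens 5 were at least 2-fold lower (median -0.68, percentile 0.045), led by Col6a2 (4.41-fold) and Col6a3 (2.99-fold). Matrix glycoproteins (6 of 17, median -0.70) included Eln, Fmod, Mfap2 and Vcan, the last 6.66-fold lower, while 1 member, the thrombospondin gene Thbs2, was 2.70-fold higher. Among basement membrane genes (3 of 13, median -0.58) the perlecan gene Hspg2 was at least 3.70-fold lower. Cholesterol synthesis genes were lower in 16 of 16 members (median -0.91, percentile 0), with Fdps 5.57-fold lower. Ribosomal protein genes had a median of -0.58 (percentile 0.71), which became -0.33 and lay inside the random range after quantile normalisation. Glycolysis and hypoxia genes were slightly higher (median 0.30, percentile 97.8), a call that 7 of the 10 alternatives fixed beforehand ended, such as no filter (median 0.23).

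**Figure D3:**
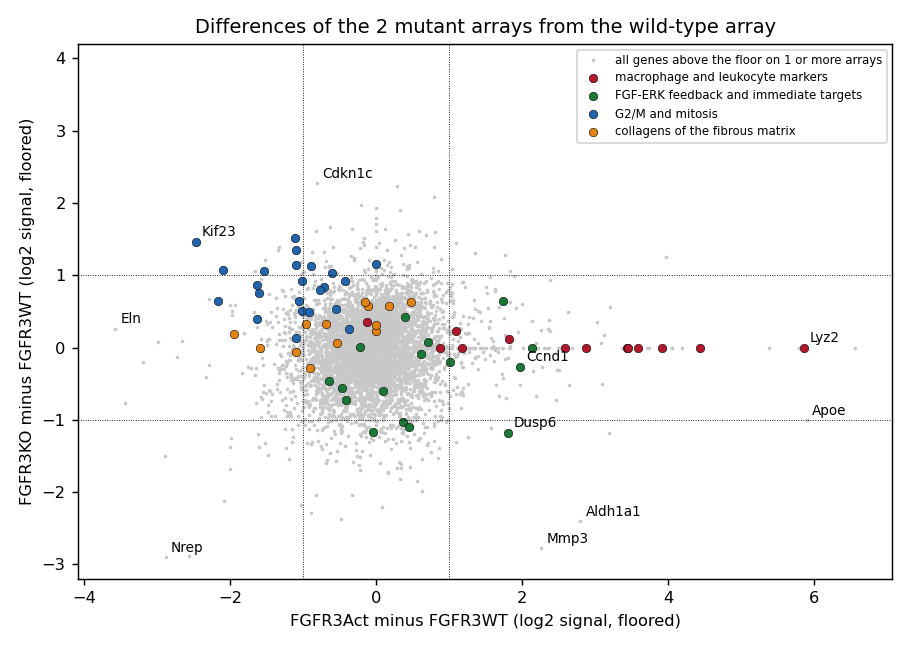
Log2 difference of FGFR3KO from FGFR3WT (vertical axis) against that of FGFR3Act from FGFR3WT (horizontal axis), 1 point per gene above the floor on at least 1 array, with signals raised to the floor, genes at the floor on both arrays of a pair drawn at 0, and dotted lines at 2-fold. Mitotic genes lie to the upper left, macrophage markers reach to the right as far as Lyz2, and Aldh1a1 and Mmp3 lie at the lower right.

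Some genes were at least 2-fold from wild type in opposite directions in the 2 mutants. In 5046 genes compared in both pairs, 8 were higher on FGFR3Act and lower on FGFR3KO: Apoe, Aldh1a1, Mmp3, Ccl9, Dusp6, the interferon-induced Ifit3, Vopp1 and the Notch effector Rbpj. Apoe, Ccl9 and Dusp6 were below the floor on FGFR3KO, so their falls are bounds (Apoe at least 2.01-fold). Their rise was on the array that held the macrophage markers. A further 13 were lower on FGFR3Act and higher on FGFR3KO, and the 10 of these furthest apart were Kif23, Cdc20, Vcan, the growth factor Mdk, the cytokinesis regulator Ect2, the amine oxidase Aoc3, Ttk, Kif20a, Kif11 and the proliferation marker Mki67. A further 6 genes were higher and 22 lower on both mutants. Among the 22 was Nrep, with signals of 602 on FGFR3Act, 594 on FGFR3KO and 4433 on FGFR3WT. Fancc was another, with 155, 151 and 656 in the same order. Such differences set the FGFR3WT array apart and do not separate the mutants. Over the 4503 genes above the floor on all arrays, the differences of the mutants from FGFR3WT correlated across genes at r = 0.0903 with a covariance of 0.0264. Shuffling the 3 values of each gene among the arrays 100 times gave a mean r of 0.499 (lowest 0.467) and a covariance of 0.189. Shuffling makes the 3 columns alike, so an r near this value follows from sharing a column, whatever the data. Of these 4503 genes, 5 were at least 2-fold higher on FGFR3Act and lower on FGFR3KO, against 4.23 for independent lists and 2.34 in the shuffled arrays, and 7 were lower on FGFR3Act and higher on FGFR3KO, against 2.94 and 2.32. In the same direction, 15 were at least 2-fold lower on both mutants against 7.02 for independent lists, and 5 were higher on both against 1.78. The shuffled arrays gave means of 46.05 lower and 72.28 higher on both. Their shared column is a mix of the 3 arrays, into which the changes of either mutant enter. The shuffled r, covariance and counts are therefore not a like reference for mutants that share FGFR3WT. Part of the excess over independent lists may come from the shared array, which could not be split.

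Probe sets of the same gene gave a technical check. Among genes at least 2-fold apart that had another measured probe set, all of these differed in the same direction for 39 of 43 genes in FGFR3Act against FGFR3WT, 19 of 21 in FGFR3KO against FGFR3WT and 78 of 92 in FGFR3Act against FGFR3KO. The others were also 2-fold apart for 23, 1 and 39 genes. Over all genes with another measured probe set, differences correlated across genes at r = 0.622, 0.396 and 0.586 in the same order. None of the genes furthest apart named above had another measured probe set.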

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

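The tests of scaling, of a fibroblast response, of dilution, of culture density and of macrophage RNA as a source of the FGF-ERK difference were chosen only after the result was seen.

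Signals outside the comparisons differed between the arrays. The control probe sets for 18S ribosomal RNA stood, as ratios of FGFR3KO to FGFR3WT, at 2.43 at the 3' end, 1.65 in the middle and 2.44 at the 5' end, and on FGFR3Act at 1.12, 0.674 and 0.501. The beta-actin controls had 3' to 5' ratios of 1.44 on FGFR3Act, 1.82 on FGFR3KO and 1.64 on FGFR3WT. Among probe sets with no gene symbol or several, 31 were at least 2-fold higher and 33 lower on FGFR3Act than on FGFR3WT, of 484 compared, and 6 were higher and 16 lower on FGFR3KO, of 460 compared.

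Macrophage markers were higher on the FGFR3Act array. A second list of macrophage genes, sharing no member with the fixed lists, was also higher, with 21 of 33 compared members at least 2-fold higher and a median at percentile 100, so macrophages in the FGFR3Act culture are a candidate explanation. The scaling of the arrays is argued against as the whole cause, since the median of the fixed list was at least 2.85 under the 3 other scalings. Leukocytes of other kinds in a like share are argued against, since 2.70% of the 37 lymphocyte, mast cell and neutrophil genes on the array were at least 2-fold higher, against 41.2% of the 51 genes of the second macrophage list, but 1 of the 7 that could be compared was (S100a8, at least 2.53-fold), with Cma1 at least 1.83-fold and Camp 1.75-fold higher, so a small number of such cells stays open. A response of the fibroblasts to active FGFR3 cannot be told apart from macrophages, because there was 1 unsorted FGFR3Act culture or pool.

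Mitotic genes were lower on FGFR3Act and higher on FGFR3KO. Dilution of fibroblast RNA by other cells on the FGFR3Act array would lower fibroblast markers alike, but 1 of 13 was as far below FGFR3WT as the mitotic median. Under the 3 other scalings the mitotic median nearest to 0 was -1.002 for FGFR3Act and 0.88 for FGFR3KO, which argues against the scaling of the arrays as the whole cause. A difference in culture density or passage may also set these genes and cannot be told apart from the genotype with 1 column per genotype.

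By its median, the list of FGF-ERK feedback and immediate targets was higher on FGFR3Act and lower on FGFR3KO. Of its members, Dusp6 alone was at least 2-fold apart from FGFR3WT both ways. Between the mutants, 13 of 16 members were higher on FGFR3Act and 3 lower. In log2 differences from FGFR3WT on FGFR3Act and FGFR3KO, the 3 were Spry4 (0.40 and 0.42), Spred2 (-0.65 and -0.46) and Etv4 (-0.22 and 0.0057). Macrophage RNA is argued against for the FGFR3KO part by the drops from FGFR3WT to FGFR3KO, as a percent of the FGFR3Act signal. The FGF-ERK genes dropped by a median of 15.9%, and the 12 macrophage genes abundant on FGFR3Act by at most 1.65%. The FGF-ERK drops used signals raised to the floor. The macrophage drops used signals as deposited, many of them below the floor. For the FGFR3Act part, members measured on both arrays lay at percentile 99.8, but macrophages express many of these genes, so macrophage RNA may contribute and cannot be told apart. That the genes follow receptor activity is a hypothesis.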

How the results depend on the processing

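The setting without macrophage genes was chosen after the data were seen; the other 10 were fixed beforehand. No paired analysis was possible because each genotype has 1 array column, and for the same reason no array could be left out. Among the settings compared, the height of the floor and the offset in its place moved the counts most. At least 2-fold higher and lower were 458 and 432 genes (FGFR3Act against FGFR3WT) and 271 and 321 (FGFR3KO against FGFR3WT), with 614 lower in FGFR3Act against FGFR3KO, with the floor at the 20th percentile. The floor at the 60th gave 118 and 140, 50 and 93, and 274 and 234 in the same order of pairs, and the offset without a floor 507 and 450, 322 and 327, and 705 and 650. With both arrays above the floor, 137 were higher in FGFR3Act against FGFR3WT. The correlation of the differences of FGFR3Act and of FGFR3KO from FGFR3WT was 0.159, 0.0575 and 0.201 under the 20th, the 60th and the offset. The other counts stayed within 1.5 times, but in FGFR3Act against FGFR3WT higher genes outnumbered lower ones under quantile normalisation (231 and 212), median centring (248 and 194), cyclic loess (246 and 195), the 20th and the offset, and not under the other settings. Without macrophage genes 182 were higher in FGFR3Act against FGFR3WT and 409 in FGFR3Act against FGFR3KO.

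Of the list medians that stood apart, 397 values under alternatives stayed outside the random range on the same side. The following moved inside it, keeping their sign unless said to reverse. For FGFR3Act against FGFR3WT, basement membrane genes had -0.35 (20th), -0.30 (60th), -0.24 (offset) and -0.35 (without _s_ and _x_ probe sets). Collagen processing had -0.34 under both the 20th and the offset, and Hox genes 0.22 (60th) and 0.0222 (no filter). The median of TGF-beta targets and pathway, FGFR3Act against FGFR3WT, was 0.13 (offset) and 0.0472 (no filter). Complement had 0.0222 with no filter and reversed to -0.23 with both arrays above the floor and to -0.0619 without macrophage genes. For FGFR3KO against FGFR3WT, FGF-ERK genes had -0.23 (60th), Hox genes 0.0592 (60th) and 0.0136 (no filter), chondrocyte markers 0.66 (both arrays) and 0.0136 (no filter), and skeletal muscle markers 0.54 (20th), 0.32 (offset) and 0.0136 (no filter). For FGFR3Act against FGFR3KO, CREB targets had 0.33 (20th), 0.16 (offset) and 0.00864 (no filter), and complement 0.00864 (no filter), reversing to -0.47 (both arrays) and -0.0794 (without macrophage genes). Glycolysis and hypoxia had 0.31 (quantile), 0.26 (20th, 60th, offset and both arrays) and 0.23 (no filter, and without _s_ and _x_ probe sets), and ribosomal proteins -0.33 (quantile). No filter adds genes at the floor on both arrays, which pulls medians to 0, and complement loses C1qa, C1qb and C1qc in both settings that reverse it; for the rest the cause was not tested. Another 28 values of lists inside the random range moved outside it. Of the named genes, 686 values kept their direction and the 2-fold size, 9 fell under it and 0 reversed. These genes were chosen as far apart, and the changes of filter leave a gene's own difference as it was. The counts therefore say nothing about whether a difference would repeat in other cultures. The macrophage list gave no value in FGFR3Act against FGFR3WT with both arrays above the floor.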

Other observations

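The test of imprinted genes was planned before its result was seen, on a list written after the genes that prompted it. Genes named in this part were chosen after their values were seen, except members furthest apart in their list.

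The list of Hox and related positional genes had a higher median on each mutant array than on the FGFR3WT array. Both differences use that 1 array, on which Hoxa6, Hoxb5, Hoxb6 and Hoxc8 were below the floor, so they are not separate findings, and FGFR3Act against FGFR3KO lay inside the random range (median 0.25, percentile 90.6). Of 13, 3 were at least 2-fold higher on FGFR3Act (median 0.51, percentile 99.8), namely Hoxb7 (2.28-fold), Hoxb6 (at least 2.25-fold) and Hoxc8 (at least 2.01-fold). Of 12 on FGFR3KO, 1 was, Hoxb5 (at least 2.54-fold, median 0.59, percentile 99.96). Tbx15 was lower on both, with log2 differences of -0.44 on FGFR3Act and -0.69 on FGFR3KO. Both Hox calls ended with the floor at the 60th percentile (0.22 and 0.0592) and with no filter (0.0222 and 0.0136). Chondrocyte markers (median 0.65, percentile 98.9, led by Col9a3 at 1.66-fold) and skeletal muscle markers (median 0.48, percentile 99.6, led by Acta1, also in the contractile list, and Myod1) were higher on FGFR3KO, each with 4 members of which 0 were 2-fold apart. The chondrocyte call ended with both arrays above the floor (0.66) and with no filter (0.0136), and the skeletal muscle call with the floor at the 20th percentile (0.54), with the offset (0.32) and with no filter (0.0136). Pericyte markers were lower on FGFR3Act than on FGFR3KO (4 members, median -0.87, percentile 0.42), led by Myh11 (at least 3.02-fold), also in the contractile list. In this pair the macrophage markers were higher on FGFR3Act (median 2.86). Of 109 list medians 40 stood apart, where lists of separately drawn genes would give 5.45. Genes of a list can vary together and the pairs share arrays, so 5.45 is not the number to be had without an effect of genotype.

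Several fixed lists lay inside the random range against FGFR3WT in both mutants. The interferon list had medians of -0.24 on FGFR3Act, with Ifit2 5.51-fold higher, and -0.25 on FGFR3KO, with Ifi47 at least 3.25-fold lower. The WNT list had medians of -0.15 and -0.11, with Ccn4 3.03-fold lower on FGFR3Act and 2.59-fold lower on FGFR3KO. The p53 list (0.25 and -0.01), the unfolded protein response (-0.02 and -0.24) and oxidative phosphorylation (-0.21 and -0.01) did not stand apart. Genes that neighbour Fgfr3 had medians of -0.24 and -0.02, and genes that vary between mouse strains 0.03 and -0.41. The Y-linked Eif2s3y was at least 2.18-fold lower on FGFR3KO than on FGFR3WT, and Xist, made by female cells, was above the floor on all 3 arrays, with signals of 694 on FGFR3Act, 874 on FGFR3KO and 757 on FGFR3WT. The sex of the donor animals is not given in the sources used here, and a difference in sex between FGFR3KO and the other arrays was not excluded.

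Some imprinted genes were lower on FGFR3Act than on FGFR3KO, among them Cdkn1c (8.46-fold), Mest (7.90-fold) and Dlk1 (4.63-fold). A candidate explanation, that imprinted genes as a group follow the genotype, was tested on 13 others. These left out the 5 that prompted the list, which also held Meg3 and Slc38a4. Their median for FGFR3Act against FGFR3KO lay at percentile 64.0, which argues against a shift of the whole group. A median cannot exclude a smaller set that moves together. With the 5 included, 6 of 18 were at least 2-fold lower and 1 higher.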
